A study of Canis lupus familiaris with 6 samples.

How the data were processed

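The series holds 6 samples of canine mammary cancer cells. Cells of the lines CMT-U27, CMT-U309 and P114 were stained for stem cell antigen 1 (Sca1) and sorted by flow cytometry into Sca1+ and Sca1- fractions, per the labels. The labels name the Sca1+ cells as cancer stem cells and the Sca1- cells as the control. Each line gave 1 sample per fraction, so there were 3 samples per fraction and 2 per line. Total RNA was labelled and hybridized to Agilent arrays with 289 canine miRNAs on 656 probes and 11560 spots other than controls. All 6 arrays lay on 1 slide and had 1 scan date, so slide and scan were shared by every sample. The labels call the 2 P114 samples cells grown with macrophages in their descriptions, while titles and sources say nothing of macrophages, and call the other samples mono-culture. The labels also name the dye Cy5, while each scanner file holds 1 green channel. Neither point was settled. The labels call the samples biological replicates without saying how the cultures were separated, so p-values measure only the spread between these samples.

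The deposited scanner files give spot intensity from Agilent Feature Extraction, version 10.10.1.1 per the file headers and 10.7.3.1 per the submitters' processing notes. The processed intensity is background-subtracted and spatially detrended, per the file headers, and is not scaled between arrays. The files also give a total gene signal per miRNA, set to 0.1 where the miRNA was not detected, and a detection flag. The deposited value table holds intensity for 311 features, controls included, with 1 column per sample. Every column equalled the total gene signal of exactly 1 scanner file for all 311 features (relative tolerance 0.0001), so the table is linear, uncentred and not scaled between arrays. The median of each column was 0.1.

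The table and the scanner files assign arrays to samples differently. 2 of the columns equalled the scanner file attached to the same sample, and 4 equalled the scanner file of another sample. The main fits followed the scanner files as attached (the scanner-file reading). The assignment of the table (the value-table reading) was run as an alternative chosen after the data were examined, and nothing in the sources used here settles which is right. Arrays are named B1, B2 and B3 (bright) and D1, D2 and D3 (dim), a bright array being one with over 50 detected miRNAs, a limit also chosen after the data were examined. By scanner file, D1 and D2 were Sca1+ and Sca1- of CMT-U27, B1 and B2 were Sca1+ and Sca1- of CMT-U309, and D3 and B3 were Sca1+ and Sca1- of P114. By value table, D1 and B2 were Sca1+ and Sca1- of CMT-U27, D2 and D3 were Sca1+ and Sca1- of CMT-U309, and B1 and B3 were Sca1+ and Sca1- of P114. The fraction was the same in both readings for 4 arrays (D1 and B1 as Sca1+, B2 and B3 as Sca1-). The line was the same for 2 (D1 and B3). By value table, all Sca1+ samples (D1, D2 and B1) lay in slide row 1 and all Sca1- samples (B2, D3 and B3) in row 2. CMT-U27, CMT-U309 and P114 lay in slide columns 2, 3 and 4. In that reading the fraction cannot be told apart from the slide row, nor the line from the slide column.

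Processed intensities at or below 0 were set to the lowest positive value of the array, and log2 was taken. Each array was scaled by its 75th percentile over the probes well above background on all 6 arrays, which left 10 probes of 6 miRNAs (let-7a, let-7b, miR-21, miR-149, miR-223 and miR-494). Spots of a probe were averaged on the log2 scale, without control spots and outlier-flagged spots, and a miRNA took the value of its probe with the highest mean. miRNAs detected on at least 3 arrays were tested, which left 80. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with files read by the R package data.table (version 1.17.8). The model had a term for line and a term for fraction, leaving 2 residual degrees of freedom. The line pairs the samples because both fractions were sorted from it. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The fit without the 3 dim arrays compared B1 with B2 and B3, was rescaled over those arrays, tested the 90 miRNAs detected on at least 2 of them and had 1 residual degree of freedom. Its p-values rest on the spread between B2 and B3 and assume that the lone Sca1+ array varies alike.

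Before the data were examined, 22 miRNA lists were fixed: miR-200 family, miR-183 cluster, other epithelial, let-7 family, miR-17 cluster and paralogues, pluripotency, miR-34 and miR-449, miR-15 with miR-16, miR-195 and miR-497, miR-221 with miR-222, miR-23 with miR-24 and miR-27, miR-29 family, miR-30 family, miR-181 family, miR-10 with miR-99, miR-100 and miR-125, miR-130 with miR-148, miR-152 and miR-301, mesenchymal and stromal, leukocyte and macrophage, erythroid, endothelial, muscle with nerve, liver and pancreas, the DLK1-DIO3 imprinted cluster, and the X-linked miR-506 to miR-514 cluster. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The rule for named miRNAs was also fixed then. It takes the largest changes among those past the threshold. For the Sca1 contrast it fills up with up to 8 miRNAs, by mean change, that moved the same way in all 3 lines. The other 4 of the 12 that did so are let-7a and let-7f, named among the brightest, and miR-10b and miR-23b, named as list members. It adds up to 4 tested members per list by mean level, with up to 6 list members past the threshold, the 10 smallest p-values of the test among lines, and the 5 brightest miRNAs. Other names were chosen after their values were seen, and the text says where.

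A miRNA not detected on a whole side of a comparison has only a bound there. Its fold is given as at least N-fold, computed from scaled log2 values, with the undetected side set on each array to the higher of its own value and the lowest value among probes well above background. Alternatives fixed beforehand were normexp background correction (offset 50), quantile scaling, scaling over all probes, no scaling, the mean of all probes, the total gene signal, the value table itself, other detection filters, a trended robust eBayes, fits without line or without fraction, the slide row in place of the line, and arrays or lines left out. A floor at the lowest signal well above background, fits without dim or disputed arrays and fits with the value-table assignment were added after the data were examined. Positions are those of the probe mappings in the files, on the canFam2 build.

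The number of arrays limits the precision. The tests were checked on simulated data with the residual spread of these arrays and 20 changed miRNAs, with 1 data set drawn per size of change. The simulated noise was independent between miRNAs and arrays, with no detection floor and no shift of whole arrays. B1 was given the spread between B2 and B3. The shares below leave out these features of the dim arrays and of the lone Sca1+ array. For the Sca1 contrast on 6 arrays, over 80 miRNAs, changes of 2 and of 4 log2 units were recovered in 0% of cases and changes of 8 log2 units in 60%. For B1 against B2 and B3, over 90 miRNAs, changes of 1 log2 unit were recovered in 0%, of 2 in 75% and of 4 in 90%, with 1 false call at each of the latter sizes.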

Results

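miRNA levels were measured in Sca1+ and Sca1- cells sorted from 3 canine mammary cancer cell lines, CMT-U27, CMT-U309 and P114. Sca1 is a surface antigen used to sort stem and progenitor cells, and the series asks which miRNAs differ in the cells it marks. The arrays fell into a bright and a dim set. B1, B2 and B3 detected 111, 91 and 89 miRNAs, with summed total gene signals of 69282, 70794 and 70162 intensity units. D1, D2 and D3 detected 39, 22 and 9 miRNAs, with summed signals of 3228, 1277 and 319.5. Of all miRNAs, 165 were detected on no array, 124 on at least 1 and 9 on all 6 (let-7a, let-7b, let-7f, miR-21, miR-23a, miR-149, miR-223, miR-365 and miR-494).

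**Figure D1:**
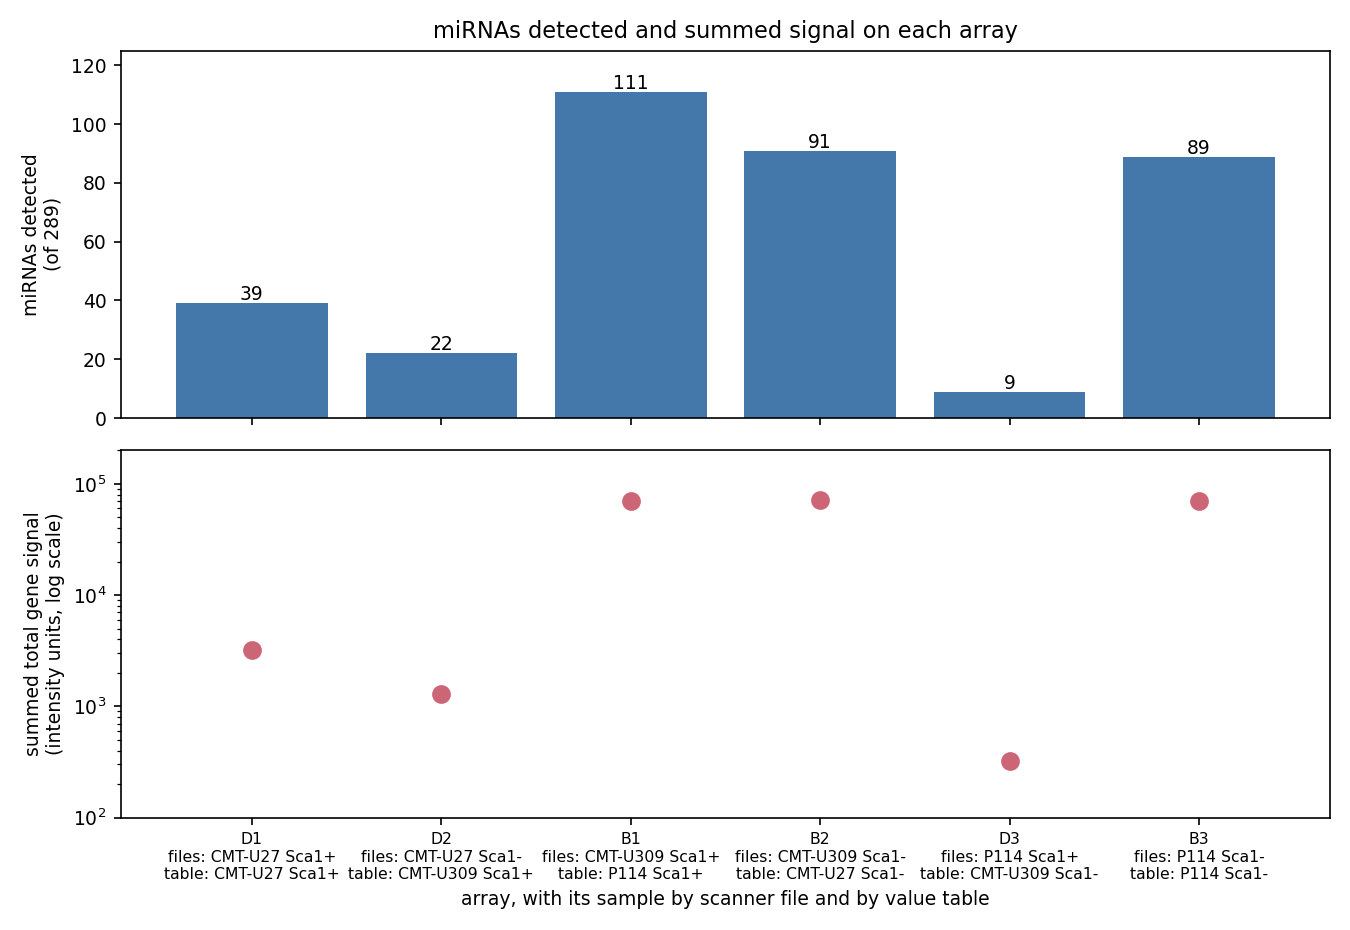
Number of miRNAs detected (top, bars from 0) and summed total gene signal (bottom, intensity units, log axis) on each of the 6 arrays, labelled by the sample that the scanner file and the value table give it. B1, B2 and B3 detected 89 to 111 miRNAs and D1, D2 and D3 detected 9 to 39.

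The brightest miRNAs over the 6 arrays were miR-21, miR-23a, miR-494, let-7a and let-7f. miR-21, a miRNA abundant in many tumours, lies on chromosome 9 (37662768 to 37662786). Its total gene signal was 18172 on B1, 32139 on B2, 31945 on B3, 646 on D1, 113 on D2 and 60.3 on D3. It made up 26.2% of the summed signal on B1, 45.4% on B2 and 45.5% on B3. miR-23a ranged from 14.6 on D3 to 5470 on B3, let-7a from 28.5 on D3 to 4537 on B1, let-7f from 12.6 on D3 to 3452 on B1, and miR-494 from 57.7 on D3 to 2723 on B1.

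Sca1+ and Sca1- cells were compared over all 6 arrays, within lines. No miRNA passed. Of the 80 miRNAs tested with limma, 0 passed the threshold, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.995. 12 of 80 miRNAs moved the same way in all 3 lines, where chance alone gives 25% of miRNAs. All 12 had lower values in Sca1+ cells and none passed. The one-sided count goes with a shift of all tested miRNAs that depends on the processing, since their median log2 difference was -0.81 in the main fit, 0.60 with normexp background and 0.31 with a floor at the detection limit. 2 of them were detected on all 6 arrays. let-7a had a mean log2 difference of -0.68 (SE 1.66, adjusted p = 0.995 with limma, n = 3 pairs) and let-7f one of -0.58 (SE 1.66). Differences within the lines were -0.74, -0.13 and -1.17 for let-7a in CMT-U27, CMT-U309 and P114. The other 10 were miR-34a, miR-99a, miR-26a, miR-155, miR-26b, miR-30b, miR-188, let-7e, miR-10b and miR-23b, which were at the floor on at least 1 array, so their sizes have no order. The other bright miRNAs did not move alike. miR-21 differed by 0.63, -1.54 and -3.23 in the 3 lines (mean -1.38, SE 1.77), miR-23a by 0.02, -0.88 and -2.43, and miR-494 by -2.08, 0.94 and 1.18.

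By the value-table reading the same contrast also gave 0 miRNAs past the threshold, with 3 at an unadjusted p under 0.05. None of the 9 lists with enough tested members passed by the scanner-file reading, and no list had a member past the threshold when adjusted over the list alone. The smallest adjusted p was 0.541 with camera and 0.993 with an estimated correlation. The medians given next take in miRNAs undetected on at least 1 array, so their sizes have no order. No member of the miR-183 cluster was detected on D1, D2 or D3. Of the 9 lists, only the let-7 family and miR-23 with miR-24 and miR-27 had a member detected on D3. The list of miR-10, miR-99 and miR-125 had a median log2 difference of -1.90, the miR-183 cluster one of -1.71, and the list of miR-23, miR-24 and miR-27 one of -1.32. Medians were -0.86 for the miR-29 family, -0.68 for the let-7 family, -0.65 for the list of miR-130, miR-148 and miR-301, -0.62 for the miR-15 and miR-16 list, -0.29 for miR-17 and paralogues and -0.22 for the miR-30 family. For 4 lists (miR-17 and paralogues, miR-15 and miR-16, the miR-30 family, and miR-130 with miR-148 and miR-301), camera gave the direction as up, against the median of all tested miRNAs. By the value-table reading 1 list passed, miR-17 and paralogues, as higher in Sca1+ (adjusted p = 0.0428), and its adjusted p was 0.969 with an estimated correlation.

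The lines were compared next, with the fraction as a term. By the scanner-file reading no miRNA passed the test among the 3 lines (smallest adjusted p 0.888, with 4 miRNAs at an unadjusted p under 0.05). The 10 smallest p-values belonged to miR-155, miR-489, miR-324, miR-24, miR-182, miR-185, miR-148b, miR-210, miR-140 and miR-34a. Every one was undetected on at least 1 array, so no fold is given. miR-489 had signals of 122 on D1, 133 on D2 and 39.2 on B1 and was not detected on the other arrays. miR-182, of the miR-183 cluster of sensory and epithelial cells, was detected on B1, B2 and B3 alone, at 233, 73.2 and 71.7. In the pairs of lines, 0 miRNAs passed for CMT-U309 over CMT-U27 (9 unadjusted), 0 for P114 over CMT-U27 (0 unadjusted) and 0 for P114 over CMT-U309 (0 unadjusted). For CMT-U309 over CMT-U27, 5 miRNAs passed as higher when either array of P114 was left out: miR-24, miR-155, miR-182, miR-185 and miR-210. Both ways of leaving out give the same fit for this pair and count as 1 result. By scanner file both CMT-U27 arrays are dim and both CMT-U309 arrays bright. All 5 were undetected on D1 and D2, so these calls set bright arrays against dim ones.

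The value-table reading gave other results for the lines, with limma as before. There 14 miRNAs passed the test among lines, 14 were lower in CMT-U309 than in CMT-U27, and 22 were higher and 2 lower in P114 than in CMT-U309. P114 over CMT-U27 gave 0. Among them were miR-17, miR-18a, miR-92a, miR-93 and miR-106a, of the miR-17 and related clusters that promote proliferation, and miR-222. Both CMT-U309 arrays are dim in that reading, and the direction turned with the treatment of low signals. With normexp background, 63 miRNAs were higher and 1 lower in CMT-U309 than in CMT-U27, and 1 was higher and 67 lower in P114 than in CMT-U309.

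None of the 9 lists passed in any pair of lines by the scanner-file reading. The lowest adjusted p was 0.0796, for miR-17 and paralogues in P114 over CMT-U27 (median log2 difference -0.53 over 10 miRNAs, adjusted p = 0.989 with an estimated correlation). For P114 over CMT-U309 the let-7 family had a median of -0.15 and miR-17 and paralogues one of -3.81, both at an adjusted p of 0.140. No member of miR-17 and paralogues was detected on D2 or D3, so its medians of -0.53 and -3.81 are not exact. For CMT-U309 over CMT-U27 the smallest adjusted p was 0.670 with camera. By the value-table reading miR-17 and paralogues was lower in CMT-U309 than in CMT-U27 (adjusted p = 0.0130, and adjusted p = 0.954 with an estimated correlation), and no list passed in the other pairs. The direction that camera gave went against the sign of the median for 4 lists in CMT-U309 over CMT-U27 (let-7, miR-17, miR-29 and miR-30) and 4 in P114 over CMT-U309 (let-7, miR-23 with miR-24 and miR-27, miR-29 and miR-30). In P114 over CMT-U27 it did so for miR-30, and for the miR-15 and miR-16 list and the list of miR-10, miR-99 and miR-125 median and mean differed in sign. The P114 samples are described as grown with macrophages, so the leukocyte and macrophage list was read in P114 over CMT-U27. It had 2 tested members: miR-223, a myeloid miRNA, differed by -0.92 (SE 2.61) and miR-155, induced in activated leukocytes, by 5.39 (SE 2.44), both at an adjusted p of 0.994 with limma. In P114 over CMT-U309 the signs were opposite, 2.82 for miR-223 and -4.04 for miR-155, both at an adjusted p of 0.791. miR-155 was detected on the bright arrays alone, so its differences between lines are not exact, and the signal of miR-223 was flat over all 6 arrays, so its differences follow the scaling.

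The Sca1 comparison was then run without the 3 dim arrays, a choice made after the data were examined, leaving B1 (Sca1+) against B2 and B3 (Sca1-), labels that hold in both readings. B1 shares its line with B2 by scanner file and with B3 by value table, and B2 and B3 come from different lines in both. With 1 Sca1+ array, the fraction is not separated from anything else particular to that sample. 4 of 90 miRNAs passed with limma, all lower in B1: miR-199, miR-99b, miR-34a and miR-140. The count and the direction turned with the processing: 43 were higher and 11 lower with normexp background, 3 higher and 7 lower with a floor at the detection limit, 2 higher and 6 lower among miRNAs detected on all 3 arrays, and none passed with quantile scaling or without a filter on dim probes (smallest adjusted p 0.398 over all miRNAs on the array). Another 7 miRNAs, among them miR-200c, miR-203 and miR-429, were seen on B1 and not on B2 or B3, with bounds above 1, which 6 of them kept in all 4 scalings (the bound of miR-9 was 0.895 with scaling over all probes). The names given for this comparison were chosen after their values were seen, except as members of the lists.

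miR-199, a miRNA of mesenchymal cells whose probes map to chromosomes 7, 9 and 20, had signals of 245 on B2 and 193 on B3 and was not detected on B1, at least 21.4-fold lower (adjusted p = 0.0112 with limma, n = 1 and 2). miR-99b, on chromosome 1 (108281049 to 108281063), had signals of 80.3 and 57.4 and was not detected on B1, at least 3.16-fold lower (adjusted p = 0.0112). miR-34a, a transcriptional target of p53 on chromosome 5 (65484409 to 65484427), was 13.0-fold lower on B1, with signals of 37.5 against 444 and 363 (log2 difference -3.70, SE 0.28, adjusted p = 0.0160). miR-140, known from cartilage and stromal cells, on chromosome 5 (82820560 to 82820573), was 14.8-fold lower, with 19.9 against 390 and 430 (log2 difference -3.89, SE 0.36, adjusted p = 0.0241). With quantile scaling none of the 4 passed, though the log2 differences were -4.09 for miR-34a and -4.28 for miR-140, and miR-199 was at least 26.2-fold lower. With normexp background the log2 differences shrank to -0.73 for miR-34a and -0.70 for miR-140. That of miR-199 was -0.99 and that of miR-99b had the opposite sign (0.55), neither exact since both were undetected on B1. Over 7 alternatives that kept the filter, the adjusted p of miR-34a ranged from 3.81e-06 to 0.0627 that of miR-140 from 1.57e-06 to 0.0719, that of miR-199 from 2.05e-10 to 0.0627 and that of miR-99b from 2.17e-08 to 0.0711.

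Of 123 miRNAs detected on at least 1 bright array, 25 were detected on B1 alone of the 3 and 4 on B2 and B3 but not on B1 (miR-199, miR-99b, miR-204 and miR-125a). For 18 of the 25 the bound was not above 1, so their detection on B1 alone shows no difference. All 4 of the other set had bounds above 1. The miR-200 family, which represses the ZEB factors and is typical of epithelial cells, had 1 tested member, too few for a list test. miR-141 and miR-200c lie on chromosome 27 (41110107 to 41110122 and 41110523 to 41110536). miR-141 had signals of 2839 on B1, 28.9 on B2 and 23.9 on D2 and was not detected on B3, D1 or D3. In the main fit miR-141 did not pass. It passed as higher in B1 with normexp background, with scaling over all probes and with a floor at the detection limit. It did not pass with quantile scaling, without scaling, with the mean of all probes or with the total gene signal. Its log2 difference was above 0 in each of these, but is not exact since miR-141 was undetected on B3. miR-200c had a signal of 1427 on B1 and was detected on no other array, at least 40.2-fold higher on B1 than on B2 and B3. miR-429, on chromosome 5 (59371758 to 59371775), had 338 on B1 alone, at least 5.10-fold higher. 3 of the 5 family members on the array were detected on B1, 1 on B2 and 0 on B3. Of the 7 other epithelial miRNAs, 2 were detected, both on B1 alone: miR-203, of differentiating epidermis, at 422 (at least 8.67-fold higher) and miR-205, of basal epithelium, at 101 (at least 2.10-fold higher). These miRNAs were not tested because they were detected on 1 array, so their bounds carry no p-value. Across 4 scalings the bound for miR-200c ran from 29.3 to 50.3 and that for miR-199 from 17.1 to 29.3.

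**Figure D2:**
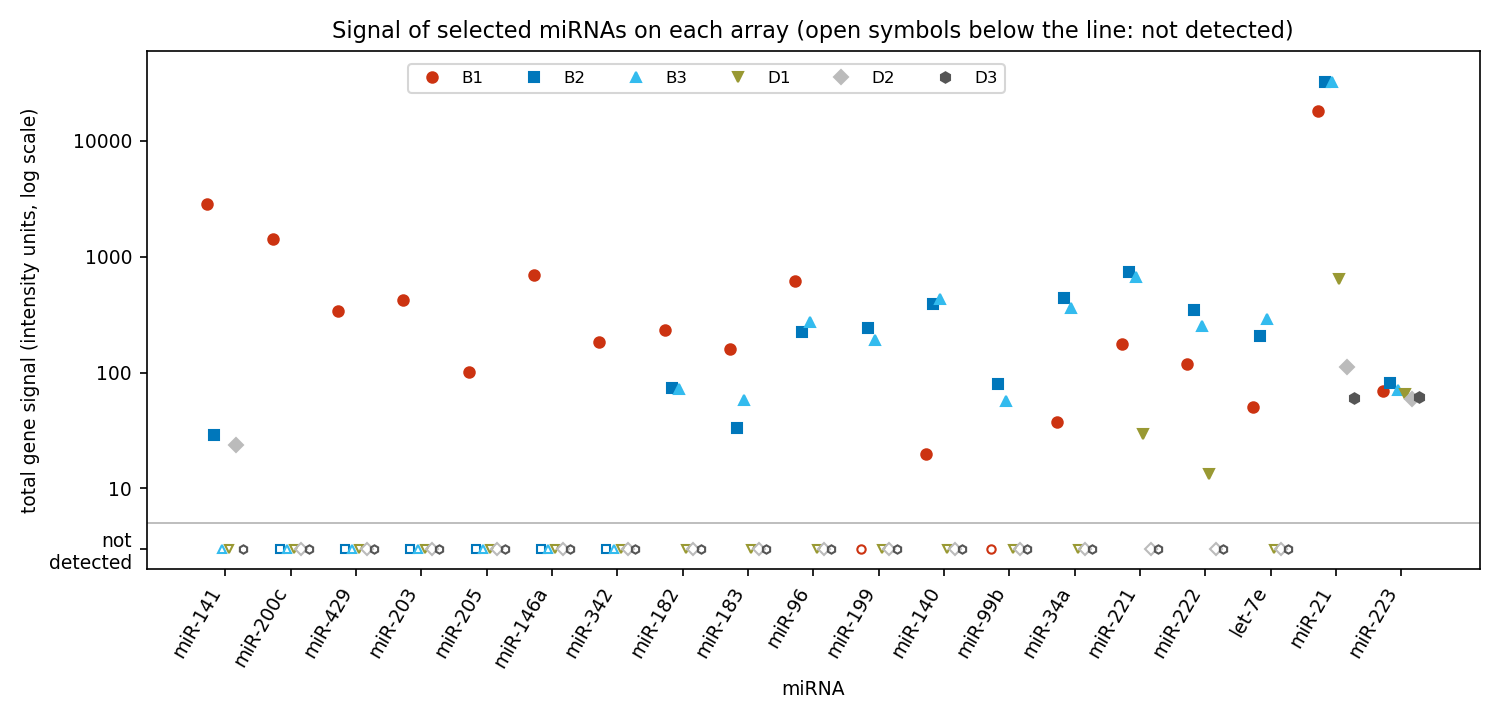
Total gene signal (intensity units, log axis) of 19 miRNAs on each of the 6 arrays, 1 symbol per array, with open symbols below the line for arrays where the miRNA was not detected. miR-200c was seen on B1 alone, at 1427, while miR-199 was seen on B2 and B3 alone, at 245 and 193.

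The mesenchymal and stromal list, 3 tested members, was the 1 list of 11 that passed with camera, as lower in B1 (adjusted p = 0.00815), and its adjusted p was 0.763 with an estimated correlation. Its tested members are miR-199, miR-140 and miR-21, the only 3 that were detected of the 7 on the array. With fry the list did not pass. With quantile scaling 2 of its 3 tested members had values below 0 and 0 above. miR-21, a member found in many cell types, was 2.22-fold lower on B1 over all tested miRNAs at an adjusted p of 0.158. In the list of miR-10, miR-99 and miR-125, which holds Hox-cluster and related miRNAs, 4 of 5 tested members had values below 0. miR-99b passed over all miRNAs tested and 2 passed adjusted over the list alone (list adjusted p = 0.138). miR-125a had 31.8 on B2 and 17.8 on B3 and was not detected on B1, at least 1.69-fold lower. miR-99a differed by -0.53, and miR-125b (-0.14) and miR-10b (0.37) changed sign between scalings. In the miR-34 and miR-449 list, miR-34a was the only member detected. miR-221 and miR-222, which repress the cell-cycle inhibitor p27, were both below the level of B2 and B3, by 4.83-fold (log2 difference -2.27, SE 0.29, adjusted p = 0.0519) and 3.14-fold (-1.65, SE 0.28, adjusted p = 0.0828). Both passed adjusted over the list alone.

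The other lists did not pass. In the miR-183 cluster all 3 members had values above 0, miR-183 at 2.56-fold, miR-182 at 2.22-fold and miR-96 at 2.01-fold (list adjusted p = 0.138), under each of the 4 scalings. All 5 members of the miR-23, miR-24 and miR-27 list had values below 0 by the main scaling, miR-27b at -0.99, miR-27a at -0.93, miR-23b at -0.62 and miR-23a at -0.60. With quantile scaling 4 of the 5 were below 0 and 0 above. With normexp background 4 were below 0 and 1 above. Of the miR-29 family, miR-29b (-1.11) and miR-29a (-0.76) were below 0, and miR-29c (-0.02) had the opposite sign without scaling (list adjusted p = 0.239). Of the let-7 family, a set that rises with differentiation, 6 of 7 had values above 0 by the main scaling and 2 of 7 with scaling over all probes. Its median was 0.25, its mean -0.07 and its adjusted p 0.629. let-7e differed by -2.54 (SE 0.51, adjusted p = 0.0905), let-7a by 0.18, let-7f by 0.25, let-7b by 0.39 and let-7c by 0.64. Of miR-17 and paralogues, 7 of 10 had values above 0 by the main scaling, 6 with quantile scaling and 10 without scaling (adjusted p = 0.139). miR-106b differed by 0.88, miR-19a by 0.63, miR-106a by -0.12 and miR-20a by -0.05, and the last pair changed sign without scaling. Values above 0 were found for 4 of 5 members of the miR-15 and miR-16 list (adjusted p = 0.375), 3 of 3 of the miR-30 family (0.608) and 5 of 6 of the list of miR-130, miR-148 and miR-301 (0.306), but for 2, 1 and 3 members with scaling over all probes. Members with the highest levels there were miR-16 (0.31), miR-15b (0.45), miR-15a (-0.11), miR-30b (0.20), miR-30d (0.03), miR-30c (0.48), miR-130a (0.34), miR-301a (0.19), miR-148a (0.55) and miR-148b (0.65). In the DLK1-DIO3 cluster 3 of 35 miRNAs were detected (miR-494, miR-370 and miR-134), all with values above 0 in the 4 scalings (adjusted p = 0.283). miR-494 differed by 0.92 (SE 0.62) and miR-370 by 0.65 (SE 0.43).

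Lists of other cell types were read by detection, without a test. Of the 7 leukocyte and macrophage miRNAs, 5 were detected, 4 of them on B1, and miR-142 and miR-150 were detected on no array. miR-223 had signals between 59.6 and 80.9 on all 6 arrays, and miR-155 had 189, 139 and 78.0 on B1, B2 and B3, with log2 differences of -0.44 and 0.39. miR-146a, an NF-kB-induced miRNA, had 690 and miR-342 had 184 on B1 alone, at least 17.3-fold and 4.22-fold higher, while miR-146b had 32.7 on B3 alone. None of the 3 endothelial miRNAs and none of the X-linked cluster, 1 miRNA on the array, was detected. Of 2 erythroid miRNAs, miR-451 was detected on D2 and B2, at 39.4 and 18.1. Of 6 pluripotency miRNAs, miR-371 was detected, on D1 alone, at 99.4. Of 15 miRNAs of muscle, nerve, liver and pancreas, miR-7 was detected on B1, B2 and B3 (log2 difference 0.37, below 0 with quantile scaling), and miR-9 (51.3) and miR-499 (12.9) on B1 alone. Of the miR-181 family, miR-181d differed by -0.41 (SE 0.36) and miR-181a had 26.9 on B1 alone. By the main scaling the bounds of miR-499 (0.395) and miR-181a (0.868) were not above 1, so no difference is shown for these 2. The median of all 90 differences was 0.18 by the main scaling, -0.04 with quantile scaling, -0.28 with scaling over all probes and 0.50 without scaling, so the sign of small differences depends on the scaling.

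B2 and B3, from different lines in both readings, were closer to each other than either was to B1. Over the 78 miRNAs detected on all 3 bright arrays, the SD of the log2 differences was 0.34 between B2 and B3, 1.01 between B1 and B2 and 1.02 between B1 and B3. Pearson's r across miRNAs, which are not independent replicates, was 0.986, 0.873 and 0.873, and Spearman's rho 0.977, 0.847 and 0.840. 2 miRNAs differed by over 1 log2 unit between B2 and B3, 15 between B1 and B2 and 16 between B1 and B3. With 1 array on a side, no test of arrays stands behind this comparison.

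**Figure D3:**
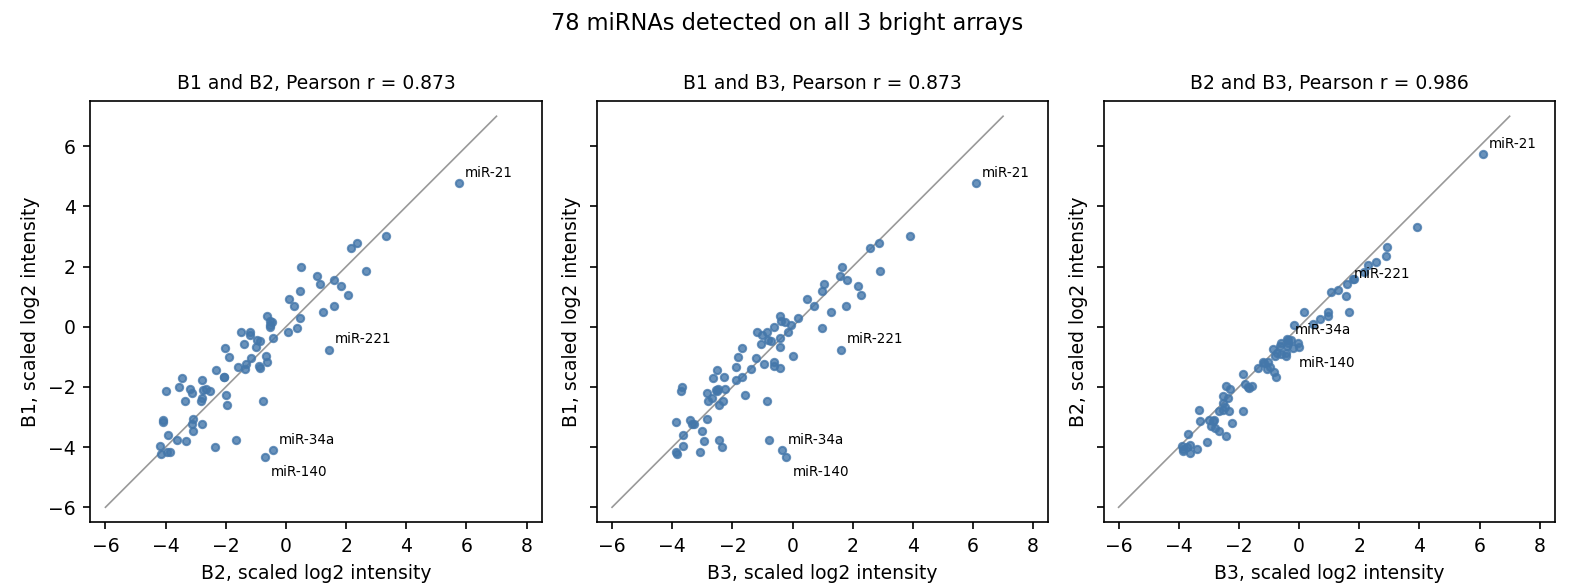
Scaled log2 intensity of the 78 miRNAs detected on all 3 bright arrays, for each pair of arrays (1 point per miRNA, grey line of equality). Points lie closer to the line for B2 and B3 (r = 0.986) than for B1 with B2 or B3 (r = 0.873 for both), and miR-34a, miR-140 and miR-221 lie below the line on B1.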

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

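All tests in this part were chosen after the values were seen. 5 control probes outside the main measurement were above the negative controls on every array and differed widely between arrays. The ratio of the highest to the lowest median signal was 71.9 for hur_1, 107.0 for hur_2, 96.1 for hur_4, 188 for hur_6 and 44.3 for mr_1, against 1.13 for the negative controls. On hur_2 the signals were 142024 on B1, 80702 on B3, 68298 on B2, 28748 on D1, 4318 on D2 and 1328 on D3. What these probes bind is not given in the sources used here.

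The first pattern weighed is that 3 of the 6 arrays detected few miRNAs. The geometric mean of the summed signal was 63.9 times higher on the bright than on the dim arrays. The spike-ins added at hybridization, dmr_3 and dmr_6, were 1.02 times as bright on the bright as on the dim arrays, which argues against poor hybridization or scanning. The spike-ins added at labelling, dmr_285 and dmr_31a, were 1.53 times as bright, far below 63.9, which argues against poor labelling as the source of the dim set. Labelling still varied between arrays, without following the bright and dim sets. dmr_285 ran from 873 on B3 to 3228 on B2, and dmr_31a from 247 on B3 to 1056 on B2. The amount and integrity of the RNA may differ between samples and were not tested, and no biological explanation was tested.

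The second pattern is that B1 differed more from B2 and from B3 than these differed from each other. Quantile scaling argues against the scaling as the source. After it, the SD of B1's differences was still at least 2.79 times that between B2 and B3. For a difference between the cell lines, B1 was set against the array of its own line, B2 or B3 by reading. Its SD was at least 2.96 times that between B2 and B3, of different lines (95% bootstrap interval over miRNAs 2.08 to 3.93). This ratio restates the pattern, and the interval does not measure the spread between arrays. If either reading is right, the labels alone go against a line difference alike in both fractions, since B1 was not closer to its own line. RNA of leukocytes on B1 stays open: miR-223 was 0.915 times the mean of B2 and B3 but had a highest over lowest signal of 1.36 over all 6 arrays, so its probe did not follow their brightness and the test is void, miR-142 was detected on no array, and miR-146a and miR-342 were seen on B1 alone. A change with the Sca1 fraction that the lines share may be present, but D1, Sca1+ in both readings, left it open. The correlation of D1 with B1 over 37 miRNAs was -0.0579 from its mean correlation with B2 and B3 (95% bootstrap interval over miRNAs -0.164 to 0.0527). miR-141 and miR-200c were not detected on D1. Of the miRNAs detected on all 3 bright arrays, all 9 at least as bright on B1 as miR-200c were detected on D1. The absence of miR-141 and miR-200c goes against sharing for this pair but comes from 1 dim array and excludes nothing. D2 did detect miR-141, at 23.9. D2 is Sca1+ by value table and Sca1- by scanner file, so it cannot decide. A change particular to 1 line, a wrong label that neither reading gives, and the slide row (row 1 for B1, row 2 for B2 and B3) also stay open and were not tested.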

How the results depend on the processing

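The alternatives with the value-table assignment, with a floor at the detection limit, without dim or disputed arrays, and all those on the bright arrays were chosen after the data were examined. The cause of a change between alternatives was not tested, except where a test is given elsewhere.

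For Sca1+ over Sca1- on 6 arrays, every alternative with the scanner-file assignment gave 0 miRNAs. Dropping the pairing by line (no replicate block) also gave 0 miRNAs and 0 lists, so the block changed no call, and the slide row in place of the line gave 0 and 0. The value-table assignment with normexp background gave 3 miRNAs (miR-141, miR-489 and miR-21), and the fit without the 3 dim arrays gave 4.

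Lists for Sca1+ over Sca1- numbered 1 in these alternatives. miR-23 with miR-27 and miR-24 was lower with normexp background, with a floor at the detection limit, and with the value-table assignment and normexp background (1 list each). The mesenchymal and stromal list was lower without a filter on dim probes and without the 3 dim arrays (1 each). miR-17 and paralogues was higher with the value-table assignment and without the 2 disputed arrays (1 each). With the value-table assignment its adjusted p was 0.969 with camera at an estimated correlation. The mesenchymal and stromal call without the 3 dim arrays was also lost at an estimated correlation. Leaving out 1 line gave 0 to 1 list.

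The test among lines gave 1 miRNA with the total gene signal (miR-489), 20 with the values and samples of the value table, 14 with the value-table assignment, 66 with that assignment and normexp background, and 55 with it and a floor at the detection limit. CMT-U309 over CMT-U27 gave 1, 20, 14, 64 and 56 miRNAs in the same alternatives, and leaving out 1 array gave 0 to 5. P114 over CMT-U309 gave 20, 24, 68 and 55 in the last 4 of these, and P114 over CMT-U27 gave 1 with the total gene signal. With the value-table assignment the direction of most miRNAs turned between the main background and normexp.

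For lists, CMT-U309 over CMT-U27 gave 1 with normexp background, 1 with the value table, 5 without a filter on dim probes, 1 with the value-table assignment, 1 with that and normexp background, 2 with it and a floor at the detection limit, and 0 to 1 when 1 array was left out. P114 over CMT-U27 gave 2 with normexp background (let-7 family and miR-23 with miR-27 and miR-24), 1 without a filter on dim probes, 1 without the fraction term (miR-17 and paralogues), 1 with the value-table assignment and normexp background, and 0 to 1 when 1 array was left out. P114 over CMT-U309 gave 1 with scaling over all probes (let-7 family), 3 without a filter on dim probes, 1 with the value-table assignment and normexp background, 1 with it and a floor at the detection limit, and 0 to 1 when 1 array was left out.

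On the bright arrays, B1 over B2 and B3 gave 54 miRNAs with normexp background (43 higher, 11 lower), 3 of them among the main 4, 0 with quantile scaling, 11 with scaling over all probes (1 higher, 10 lower), 2 with the mean of all probes, 10 with a floor at the detection limit (3 higher, 7 lower), 0 without a filter on dim probes, 8 among miRNAs detected on all 3 arrays (2 higher, 6 lower) and 7 with a trended robust eBayes.

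Of 44 named miRNAs on the bright arrays, some changed the sign of their log2 difference, in 35 cases over 7 alternatives. With scaling over all probes these were let-7a (-0.28), let-7f (-0.21), let-7b (-0.068), miR-16 (-0.15), miR-15b (-0.0037), miR-30b (-0.26), miR-30d (-0.43), miR-10b (-0.086), miR-130a (-0.12), miR-301a (-0.26), miR-155 (-0.064) and miR-7 (-0.090). With normexp background they were miR-99b (0.55), let-7a (-0.17), let-7f (-0.093), miR-15a (0.23), miR-29c (0.32), miR-181d (0.46) and miR-223 (0.72). Without scaling they were miR-20a (0.27), miR-106a (0.20), miR-15a (0.21), miR-29c (0.30) and miR-125b (0.18). With quantile scaling they were miR-30d (-0.076), miR-10b (-0.088), miR-301a (-0.10) and miR-7 (-0.22). With the total gene signal they were let-7a (-0.049), miR-30b (-0.013), miR-30d (-0.16) and miR-301a (-0.029), and with the mean of all probes miR-106a (0.039), miR-29c (0.062) and miR-125b (0.0069). Of the 4 miRNAs past the threshold, miR-99b alone changed sign.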

Other observations

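All tests in this part were chosen after values were seen. Among the 90 miRNAs tested on the bright arrays, neighbours tended to differ alike between B1 and the pair B2 and B3. On chromosome 1, miR-99b, let-7e and miR-125a lie within 653 bases and were all lower on B1. let-7e differed by -2.54 log2 units. miR-99b and miR-125a were not detected on B1 and were at least 3.16-fold and 1.69-fold lower. On chromosome 20, miR-191 and miR-425 lie 478 bases apart and had differences of 1.00 and 1.62. On chromosome X, miR-221 and miR-222 lie 639 bases apart and had -2.27 and -1.65. On chromosome 6, miR-106b, miR-25 and miR-93 had 0.88, 0.85 and 0.57. On chromosome 31, let-7c and miR-99a, 741 bases apart, had 0.64 and -0.53. Neighbours with an untested member were left out. On chromosome 5, miR-429 was seen on B1 alone, while its neighbours miR-200a and miR-200b were detected on no array.

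The third pattern weighed is this likeness. Among the 90 miRNAs, 43 pairs of 39 miRNAs lay within 10000 bases, and the median gap in log2 difference within a pair was 0.35, against 0.95 when the differences were shuffled over miRNAs. The permutation p was 0.00026 with 100000 resamples, one-sided, which argues against chance. Over the 40 pairs whose probes share no run of 10 bases the median gap was 0.36 and the permutation p was 0.00047. That argues against cross-hybridization through shared runs of this length as the source. Pairs with shorter shared runs, such as 8 bases for miR-182 and miR-183, stayed in, and such runs were not tested. 30 of the 43 pairs had the same sign. As a hypothesis, members of a cluster may be made from a shared transcript that differed between the cells on B1 and those on B2 and B3. The test does not say what set the difference between these cells.

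Some miRNAs were seen in 1 sample. miR-211 (68.7), miR-328 (75.8), miR-885 (63.8) and miR-483 (42.1) were detected on B2 alone of the 6 arrays. The signal of miR-223 on the 6 arrays had a ratio of highest to lowest of 1.36, while the summed signal had a ratio of 221.6. The same ratio for miR-149 was 3.20. Both miRNAs are among the 6 that set the scaling of the 6 arrays.

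The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 miRNAs and 0 lists past the threshold, a count that all 10 splits reach. The highest of the other splits gave 0 miRNAs and 1 list.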
